A study of Homo sapiens with 13 samples.

How the data were processed

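RNA was measured by sequencing in 13 human libraries, of which 10 came from flash-frozen meningioma tissue and 3 from first-passage cultures of arachnoid granulation cells grown in DMEM with 7% fetal bovine serum. Meningioma is a tumour of the membranes around the brain, and arachnoid granulations are the outgrowths of the arachnoid membrane that drain cerebrospinal fluid. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries. The labels describe the reads as both paired-end and single-end, and this was not resolved. The series also has matching ChIP-seq, not analysed here.

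The deposited values are TPM, a transcript abundance corrected for length and scaled to the same sum in every library, given as 1 value per gene symbol and library. Per the submitters' processing notes, Trim Galore, Salmon and DESeq2 were used with the human build hg19. The role of DESeq2 and all versions are not given in the sources used here. Each column of the table sums to 1000000. TPM keeps no depth, so the number of reads behind a value is unknown and no counting interval or detection floor is given. A gene at 0 is described only as listed at 0. TPM values of genes that share sequence with a close copy or pseudogene depend on how the quantifier split their reads, so RPL41P1, SRP9P1, TMSB4XP6, LUZP6, PIGY, C4B_2, PPIAP22 and SNRPEP4 are uncertain.

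The table holds 35106 gene symbols, of which 6968 were listed at 0 in every library. A total of 307 genes that are Y-linked or mark X inactivation were left out. Genes with at least 1 TPM in at least 3 libraries were tested, which left 15254. Values were analysed as log2(TPM + 1), so a log2 difference understates the change of genes near 0. Tissue and culture were compared with limma 3.58.1 in R 4.3.3, using an intensity trend, no covariates and Benjamini-Hochberg adjustment at 0.05. All p-values are two-sided. They measure the spread between these samples, since the labels do not say that the 3 cultures came from separate donors.

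Before the data were examined, 48 gene lists (pathways and markers of cell types that the tissue or culture could hold) were fixed. The 45 lists with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes. An estimated correlation and fry, which tests whether a list moves on balance one way, were the alternatives. The 12 relations across the meningiomas were also fixed. They were tested by Pearson's r and Spearman's rho with 100000 permutations, or exactly in sets under 10 libraries, with Benjamini-Hochberg adjustment over the 12. A list's value in a library is the mean log2(TPM + 1) of its tested members.

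The genes named were chosen by a rule fixed at the same time. It takes the 12 genes with the largest log2 difference in each direction, among genes past the threshold with no overlap between the groups and a mean of at least 10 TPM in the higher group, passing over non-coding clone names and immunoglobulin genes. It adds DUSP1, PGR, NR3C1, SSTR2, PTGDS, NF2, MKI67, CD68 and COL1A1 in any case. From each list it takes up to 4 members past the threshold with at least 5 TPM in the higher group, or 2 abundant members where none passed. It also takes the 12 genes with the largest SD between meningiomas. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen.

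The alternatives fixed at that time changed the pseudocount, the filter, the scaling (median-of-ratios factors or quantile normalization), the model (limma without the trend, robust, with array weights or with a minimum fold, and an exact Wilcoxon test), and the libraries included, leaving out each in turn and leaving out 2 meningiomas whose titles carry another prefix than those of the other 8. Alternatives chosen after seeing the data removed from each library the trend with transcript length, GC content or both, by splines with 4 degrees of freedom, or removed the 50 most abundant genes with ribosomal protein and mitochondrial genes. They also used only the 3 meningiomas whose deviations from the gene means fell with GC content, or only the other 7. Settings that leave out libraries filtered the genes again in those kept, and the set of 3 was also tested over the same 15254 genes. Median-of-ratios factors and the removal of abundant genes also filtered again, which left 15151 and 16579 genes. That removal took pseudogenes of ribosomal protein genes too. Removing a trend also centred each library, and with both removed the median log2 difference of all genes went from -1.07 to -2.99e-05. Lengths and GC content came from GENCODE 29 transcripts, matched by symbol for 13665 (89.6%) of the tested genes. This annotation is on another build than hg19, so none of its coordinates are printed, and its positions were used only to find which genes neighbour TNNT3 and which are Y-linked.

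The tests were tried on simulated data made from the means and SDs of the 15254 genes, with 200 genes changed in a comparison of 10 with 3 libraries. limma called 5.97% of the genes changed by 1 on the log2 scale, 47.8% of those changed by 2 and 92.4% of those changed by 4, with 5 calls among the 15054 unchanged genes. The exact Wilcoxon test called 0% at each size. With 286 possible splits of the libraries, its smallest p-value cannot pass the adjustment over 15254 genes when only 200 are changed. This 0% was therefore fixed in advance and does not measure the test. The simulated genes were independent and had the same SD in both groups, whereas the real median SD was 0.788 in tissue and 0.288 in culture. Far more genes were called in the real data, so these shares do not give the power there. Relations were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.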

Results

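The series holds 10 libraries of meningioma tissue and 3 of cultured arachnoid granulation cells. All tumour libraries came from frozen tissue, and all arachnoid libraries from cells grown in serum. Tumour status, tissue or culture, serum and the mix of cell types therefore change together between the groups. The comparison cannot tell these apart. A difference given below is between tissue and culture, and is not assigned to the tumour. The tissue libraries had between 9451 and 13331 genes at 1 TPM or more, and the cultures between 13119 and 13430. Symbols that begin with RPL or RPS, which include pseudogenes, took 19.99% to 48.7% of all TPM in the tissues and 8.72% to 11.3% in the cultures. The 24 cytosolic ribosomal protein genes of the fixed list took 5.52% to 11.9% in the tissues and 2.28% to 2.97% in the cultures. Mitochondrially encoded transcripts took 1.43% to 4.15% in the tissues and 6.60% to 13.7% in the cultures. Spearman's rho across genes, which are not independent replicates, had a median of 0.767 between tissues, 0.934 between cultures and 0.455 between a tissue and a culture. With the cultures, meningiomas 1 to 3 had a median rho of 0.671 and the other 7 of 0.431. Between the 7 and the 3 the median was 0.704, against 0.862 within the 7 and 0.842 within the 3.

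The first comparison asked how the transcripts of the tumours differ from those of the cultured cells. Genes of macrophages and antigen presentation led the higher side. C1QA, a subunit of the complement protein C1q made by macrophages, averaged 393 ± 301 TPM (SD, n = 10) in tissue and 0.687 ± 0.191 (n = 3) in culture. CD74, the invariant chain of MHC class II, averaged 647 ± 403 and 5.44 ± 0.46 TPM. On the lower side, TFPI2, a protease inhibitor, averaged 0.701 ± 0.446 TPM in tissue and 698 ± 442 in culture. LAMC1, a laminin chain, averaged 6.29 ± 7.13 and 1119 ± 535 TPM.

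The 12 leading higher genes had log2 differences between 6.13 and 7.43. After C1QA they were RARRES2 (chemerin), STAB1 (a scavenger receptor), the complement component C3, C1QB, LST1, CD74, the protease inhibitor SLPI, HLA-DRB1, the haemoglobin gene HBA2, RNASE1 and HLA-DRA. C1QA differed by 7.43 ± 0.66 (SE, limma adjusted p = 5.41e-07) and RARRES2 by 6.96 ± 0.63 (adjusted p = 6.45e-07). SLPI ranged between 28.1 and 15088 TPM in the tissues, and with only meningiomas 1 to 3 it differed by 4.21 against 6.38 with all 10, and lost its call over the same genes (adjusted p = 0.0554) but not after filtering them again (adjusted p = 0.0406). The 12 leading lower genes had log2 differences between -8.52 and -7.35. They were TFPI2, ENPP2 (autotaxin), RPL41P1, RGS4, SRP9P1, the protease inhibitor SERPINE2, LAMC1, COL4A2, IGFBP1, ABI3BP, STC1 (stanniocalcin) and LMO7. TFPI2 differed by -8.52 ± 0.42 (limma adjusted p = 2.60e-09) and ENPP2 by -8.51 ± 0.52 (adjusted p = 1.39e-08). RPL41P1 was listed at 0 in 9 meningiomas, and its reads cannot be separated with certainty from those of its parent gene.

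**Figure D1:**
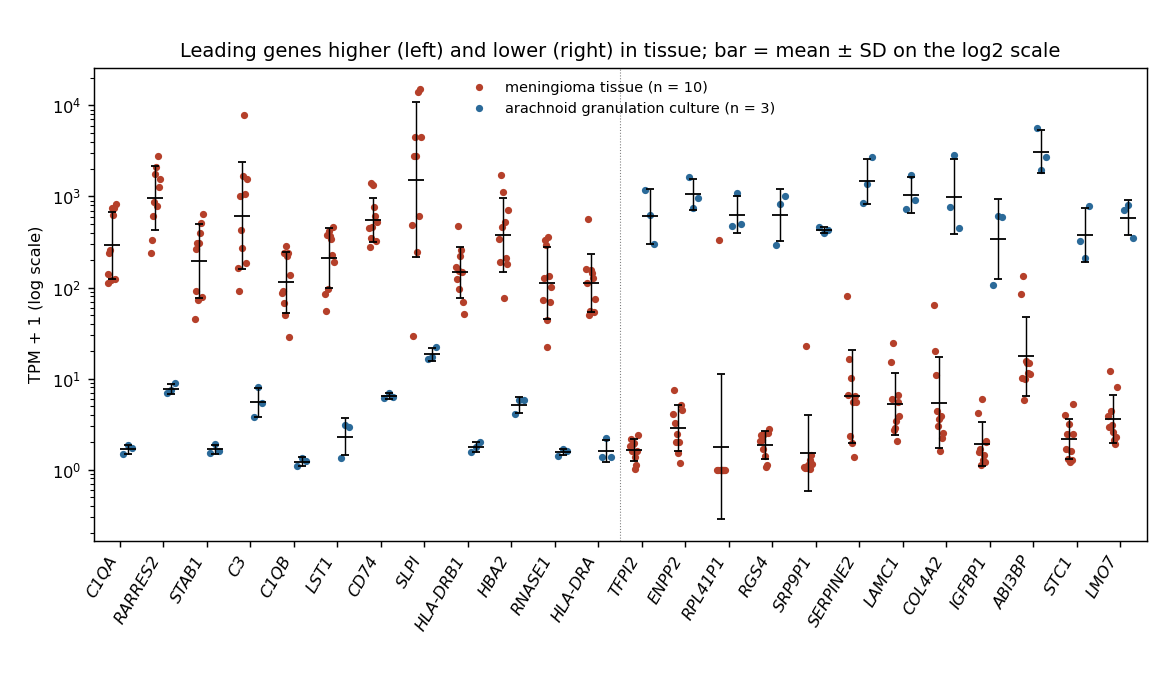
TPM + 1 on a log axis for the 12 leading genes in each direction, with a point per library and bars at the mean ± SD of log2(TPM + 1) in meningioma tissue (red, n = 10) and arachnoid granulation cultures (blue, n = 3). No tissue value of these genes overlaps a culture value, and SLPI spans 28.1 to 15088 TPM in the tissues.

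In all, limma called 8984 of 15254 genes at an adjusted p under 0.05, with 1565 higher and 7419 lower in tissue (82.6% lower). The median log2 difference of all tested genes was -1.07, and some list medians below are also given relative to it. With median-of-ratios factors the split was 3144 higher and 4510 lower (58.9% lower), and with quantile normalization 3333 and 4187 (55.7% lower). Without culture 1, 2 or 3 the higher count was 948, 1004 and 1007. Values of all 10 tissues lay on one side of all 3 cultures for 6735 genes (44.2%), where chance gives 0.699%. The share of lower genes among those called moved with base composition, from 98.3% in the quartile of lowest GC content to 46.1% in the highest. It also moved with transcript length, from 56.7% in the shortest quartile to 96.1% in the longest.

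**Figure D2:**
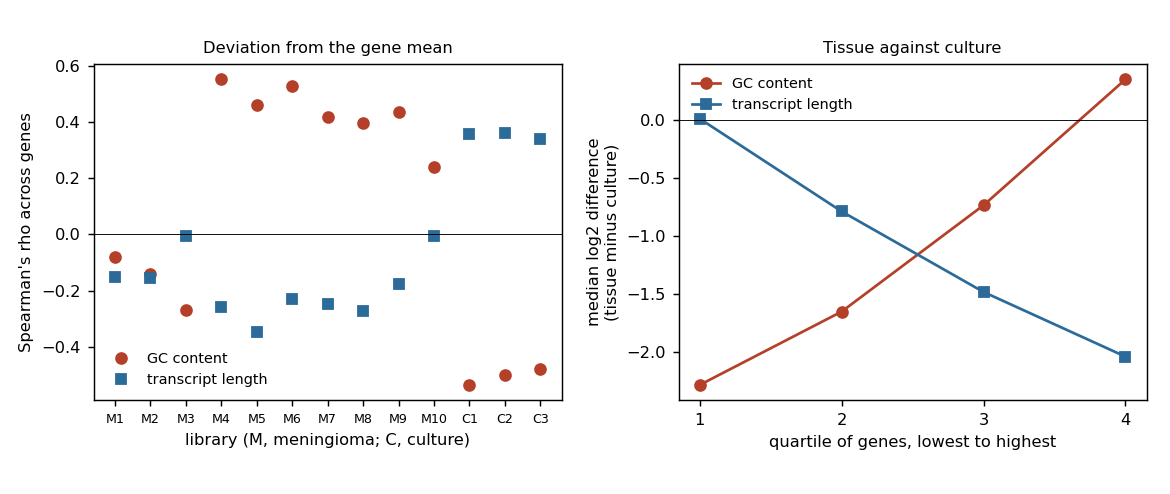
Left, Spearman's rho across genes between each library's deviation from the gene means and GC content (circles) or transcript length (squares) for 10 meningiomas (M) and 3 cultures (C). Right, median log2 difference of tissue minus culture in quartiles of genes by GC content or length, which runs from -2.28 to 0.35 with rising GC content.

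Markers of macrophages and MHC class II genes were higher in tissue. Of 16 macrophage and microglia markers, 12 were higher and 1 lower (camera adjusted p = 1.71e-11), with a median log2 difference of 3.99, or 5.06 above that of all genes. Among them, LAPTM5 averaged 84.2 ± 47.1 TPM in tissue and 0.239 ± 0.132 in culture, and AIF1 84.5 ± 46.4 and 0.363 ± 0.270. The exception was CD68, a lysosomal protein also found outside macrophages, at 15.5 ± 10.9 TPM in tissue and 40.5 ± 20.1 in culture (log2 difference -1.44 ± 0.50, limma adjusted p = 0.0217). Its call was lost without culture 3 (adjusted p = 0.149), with median-of-ratios factors (adjusted p = 0.677), with quantile normalization (adjusted p = 0.911) and after removing the GC and length trends (adjusted p = 0.0777). Of 12 MHC class II genes, 11 were higher (camera adjusted p = 1.71e-11), and HLA-DRB1 averaged 176 ± 124 TPM against 0.785 ± 0.213. With an estimated correlation, both lists had an adjusted p = 0.288.

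T and NK cell, granulocyte and endothelial markers were higher too. Of 10 tested T and NK cell markers, 5 were higher (camera adjusted p = 0.00201), including CD3D, at 10.5 ± 9.2 TPM against 0.0167 ± 0.0290, and NKG7. Of 7 granulocyte and mast cell markers, 4 were higher and 1 lower (adjusted p = 0.00580), including the calgranulins S100A8 and S100A9, with CSF3R and FPR1. Of 11 endothelial markers, 8 were higher, and 9 when adjusted over the list alone (camera adjusted p = 1.63e-05), and PLVAP, a protein of fenestrated vessels, averaged 253 ± 224 TPM against 2.39 ± 2.23. CLDN5 and PECAM1 were also higher, and PECAM1 lost its call without culture 1 (adjusted p = 0.125) or culture 2 (adjusted p = 0.11). With an estimated correlation the adjusted p was 0.288 for the T and NK cell and endothelial lists and 0.338 for the granulocyte list, and with quantile normalization the T and NK cell and granulocyte calls were lost (adjusted p = 0.0512 and 0.0680), as after removing the length trend alone (adjusted p = 0.0730 and 0.0578). Of 12 erythroid and platelet markers 4 passed the filter, too few for a list test, and HBA1, HBA2, HBB and ITGA2B were higher in tissue. HBB averaged 456 ± 1070 TPM in tissue and 2.84 ± 1.68 in culture. This tissue mean rests largely on meningioma 3, at 3466 TPM, and the tissue median was 58.9.

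Basement membrane genes and targets of YAP were lower in tissue. Of 15 basement membrane genes, 14 were lower (camera adjusted p = 0.00201), including LAMC1, COL4A2, NID2 and COL4A1, which differed by -7.00 ± 0.88 on the log2 scale. Of 16 target genes of the Hippo effector YAP, 14 were lower (adjusted p = 0.0107). NT5E averaged 6.21 ± 5.23 TPM in tissue and 574 ± 146 in culture, followed by CRIM1, TEAD1 and CTGF. Of 20 collagens and matrix genes, 15 were lower, including COL3A1, COL5A2, FBN1 and FN1, with a camera adjusted p = 0.0540 that misses the threshold. COL1A1 averaged 327 ± 591 TPM in tissue and 4637 ± 3116 in culture (log2 difference -5.03 ± 1.03, limma adjusted p = 0.00067). It reached 1948 TPM in meningioma 2, and its tissue median was 91.2. With an estimated correlation the adjusted p was 0.288 for basement membrane and 0.732 for the YAP targets, and the YAP call was also lost with only the 3 meningiomas whose deviations from the gene means fell with GC content (adjusted p = 0.107).

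Of 22 genes of the G2 and M phases, 17 were lower in tissue, and 18 when adjusted over the list alone (camera adjusted p = 0.0157). After removing the GC and length trends, which also centres the libraries, 4 were lower and 1 higher. The list median went from -1.98, or -0.91 relative to that of all genes, to -0.01, where that of all genes was -2.99e-05. The proliferation marker MKI67 averaged 0.552 ± 0.751 TPM in tissue and 8.79 ± 3.11 in culture, and CCNB1, CDK1, KIF20A and PLK1 were also lower. The list's call was lost without meningioma 3 (adjusted p = 0.0597), with a filter of 5 TPM (adjusted p = 0.233), with quantile normalization (adjusted p = 0.0726), with only the 3 meningiomas whose deviations fell with GC content (adjusted p = 0.131), and after removing the length trend (adjusted p = 0.148), the GC trend (adjusted p = 0.625) or both (adjusted p = 0.871), where MKI67 went from -2.72 ± 0.38 to -0.69 (adjusted p = 0.129, and 0.151 without the length trend alone). CDK1 lost its call with quantile normalization (adjusted p = 0.0504), and CDK1 and CCNB1 lost theirs after removing the GC trend (adjusted p = 0.299 and 0.106) or both trends (adjusted p = 0.0959 and 0.0884). With an estimated correlation the adjusted p was 0.735. Of 21 DNA replication genes, 13 were lower and 1 higher, with 15 lower when adjusted over the list alone (camera adjusted p = 0.226), and MCM4, CDC6, RRM2 and MCM6 were among the lower. After removing the GC and length trends, 4 of this list were higher and 4 lower. MCM6 lost its call with quantile normalization (adjusted p = 0.112), with only the same 3 meningiomas (adjusted p = 0.0774) and after removing the length trend (adjusted p = 0.155), the GC trend (adjusted p = 0.240) or both (log2 difference -0.40, adjusted p = 0.567).

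Cytosolic ribosomal protein genes were higher and mitochondrially encoded transcripts lower in tissue. Of 24 cytosolic ribosomal protein genes, 12 were higher and none lower (camera adjusted p = 1.13e-09). RPL13 averaged 12322 ± 6092 TPM in tissue and 1064 ± 147 in culture, and RPL18 was also higher. Of 13 mitochondrially encoded transcripts, 12 were lower (camera adjusted p = 0.048), led by MT-ND4L, MT-ATP8, MT-ND4 and MT-ND5. With an estimated correlation the adjusted p was 0.326 and 0.735. The mitochondrial call was lost with median-of-ratios factors (adjusted p = 0.181), with a filter of 5 TPM (adjusted p = 0.130), after removing the GC trend alone (adjusted p = 0.625), with only the 3 meningiomas whose deviations fell with GC content (adjusted p = 0.147) or only the other 7 (adjusted p = 0.114), without the 2 meningiomas of the other title prefix (adjusted p = 0.0595) and without meningioma 1, 3, 7 or 10 or culture 1, where the adjusted p lay between 0.050 and 0.064.

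Glucocorticoid-induced genes split. Of 16 measured, 5 were higher and 2 lower (camera adjusted p = 0.00337, and adjusted p = 0.428 with an estimated correlation). TSC22D3 (GILZ) averaged 280 ± 173 TPM in tissue and 8.23 ± 6.35 in culture, and MT1X 252 ± 189 and 12.7 ± 14.7. ZBTB16 was higher too, whereas the kinase SGK1 averaged 8.76 ± 19.6 TPM in tissue and 229 ± 47 in culture. SGK1 reached 63.7 TPM in meningioma 3, and its tissue median was 1.85. The list's call was lost after removing the GC trend (adjusted p = 0.149) or the GC and length trends (adjusted p = 0.138). DUSP1, a phosphatase that acts on MAP kinases, averaged 85.0 ± 210 TPM in tissue and 103 ± 37 in culture, a log2 difference of -2.35 ± 1.14 that missed the threshold (limma adjusted p = 0.0883). It was above the cultures in 1 meningioma and below them in 9, and without meningioma 3 the difference was called (-2.92, adjusted p = 0.00326).

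Of 6 steroid receptor genes, 5 were lower, with a camera adjusted p = 0.153. PGRMC2 and PGRMC1, membrane proteins linked to progesterone, led this group. The glucocorticoid receptor NR3C1 averaged 2.67 ± 2.40 TPM in tissue and 12.8 ± 4.1 in culture (log2 difference -2.11 ± 0.52, limma adjusted p = 0.00271), and its difference was 0.33 after removing the GC and length trends (adjusted p = 0.379) and -0.67 with quantile normalization (adjusted p = 0.17). The progesterone receptor PGR averaged 0.253 ± 0.463 and 1.32 ± 0.15 TPM, near the bottom of the scale (log2 difference -0.95 ± 0.26, adjusted p = 0.00518). After removing the length trend its difference was 0.40 (adjusted p = 0.178). These removals and quantile normalization also centre the libraries, and the median of all genes was -1.07 in the main test.

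Markers of the arachnoid and meningioma went both ways, with 6 of 19 higher and 6 lower (camera adjusted p = 0.160). After removing the GC and length trends, which also centres the libraries, 8 were higher and 3 lower. The list median went from -0.82, or 0.25 relative to that of all genes, to 1.60, where that of all genes was -2.99e-05. PTGDS, the prostaglandin D synthase abundant in the leptomeninges, averaged 62152 ± 80699 TPM in tissue and 792 ± 406 in culture (log2 difference 4.60 ± 1.48, limma adjusted p = 0.0141), and lay above the cultures in 9 of 10 tissues. Its call was lost without culture 1 (adjusted p = 0.0534) and after removing the GC and length trends (adjusted p = 0.0643). CRABP1, a retinoic acid binding protein, was higher at 444 ± 327 TPM against 29.1 ± 33.6, and lost its call without culture 1 (adjusted p = 0.151). CDH11 and DSG2, both adhesion genes, were lower. The somatostatin receptor SSTR2 averaged 11.8 ± 14 and 23.1 ± 21 TPM, and its difference did not exceed the spread (adjusted p = 0.212).

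Of 22 genes altered in meningioma, 16 were lower and 1 higher, with 17 lower when adjusted over the list alone (camera adjusted p = 0.0594). The tumour suppressor NF2 averaged 2.55 ± 2.71 TPM in tissue and 14.1 ± 1.3 in culture (log2 difference -2.42 ± 0.57, limma adjusted p = 0.0019), and CDKN2B, POLR2A and KDM5C were lower. NDRG2 was the higher member, at 26.5 ± 17.6 and 1.39 ± 0.59 TPM. Of 16 enhancer cofactors, 13 were lower, led by BRD2, CDK7, HDAC2 and MED12 (camera adjusted p = 0.0594), and the list passed after removing the GC trend alone (adjusted p = 0.0114) and with only the 3 meningiomas whose deviations fell with GC content (adjusted p = 0.0224). HDAC2 lost its call after removing the GC trend (adjusted p = 0.103) or the GC and length trends (adjusted p = 0.0736). NF2 lost its call with quantile normalization (adjusted p = 0.160).

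**Figure D3:**
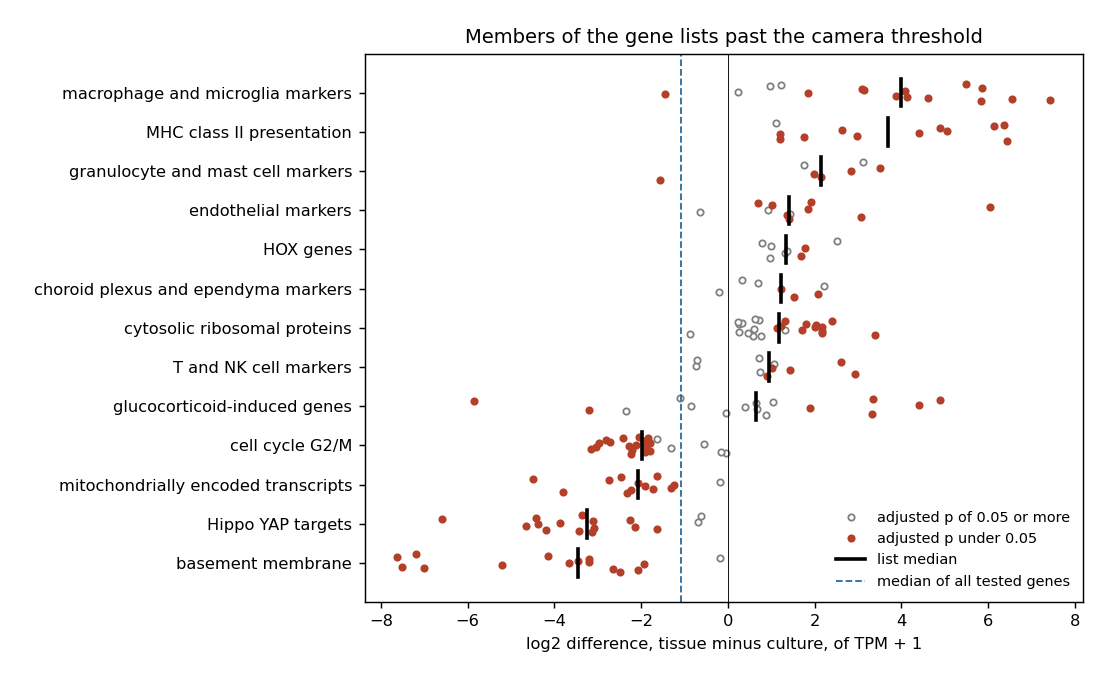
Log2 difference of tissue minus culture for each tested member of the 13 lists past the camera threshold, filled where the gene's adjusted p was under 0.05. Black bars mark list medians, from -3.46 for basement membrane to 3.99 for macrophage and microglia markers, and the dashed line marks the median of all genes at -1.07.

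Among HOX genes 2 of 8 were higher (camera adjusted p = 0.00199, and adjusted p = 0.326 with an estimated correlation). HOXC9 and HOXC10, its most abundant members, averaged 15.8 ± 19.8 and 4.44 ± 9.10 TPM in tissue and did not pass singly, though HOXC9 did without meningioma 4, 9 or 10 (adjusted p between 0.0392 and 0.0414). Of 7 choroid plexus and ependyma markers, 3 were higher, and 1 when adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.428 with an estimated correlation). CCDC153 and AQP1 were among them, and AQP1 lost its call without meningioma 4 or 8 or culture 1 or 3 (adjusted p between 0.052 and 0.245). The HOX call was lost with quantile normalization (adjusted p = 0.0636), and the choroid plexus call with that (adjusted p = 0.0825) and with median-of-ratios factors (adjusted p = 0.0704).

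In all, 13 lists passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.288. After removing the trends with GC content and length, the glucocorticoid and G2 and M phase lists no longer passed and the other 11 did. Collagens (adjusted p = 0.00225), contractile genes (adjusted p = 0.00144), senescence and p53 targets (adjusted p = 0.0107) and meningioma driver genes (adjusted p = 0.0266) then passed as well. After this removal 0 lists passed with an estimated correlation, where the adjusted p was 0.60 for collagens and 0.449 for the contractile, senescence and driver lists. Leaving out 1 library also brought lists past the threshold: collagens without meningioma 2 or culture 1 or 3 (adjusted p between 0.00496 and 0.0132), contractile genes without culture 1 or 3 (adjusted p = 0.0216 and 0.0199), driver genes without culture 2 or 3 (adjusted p = 0.0359 and 0.0391) and MHC class I genes without culture 2 (adjusted p = 0.0302). Schwann cell markers passed without culture 2 or 3 (adjusted p = 0.0405 and 0.0397), B and plasma cell markers without meningioma 2, 3 or 5 (adjusted p between 0.0457 and 0.0469), and osteoblast and chondrocyte markers without meningioma 4, 5, 8 or 9 or culture 2 (adjusted p between 0.0451 and 0.0498). Member counts adjusted over the list alone were the same as over all genes, except where given.

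Other settings also moved lists across the threshold. A pseudocount of 0.1 TPM brought collagens, B and plasma cell and osteoblast markers past it (each adjusted p = 0.0323), the filter of 5 TPM osteoblast markers (adjusted p = 0.0129), and leaving out the 2 meningiomas of the other title prefix collagens, B and plasma cell and epithelial markers (adjusted p = 0.0155, 0.0324 and 0.0461). Collagens also passed with median-of-ratios factors (adjusted p = 0.0122), and collagens and contractile genes with quantile normalization (adjusted p = 0.000677 and 0.0232). Collagens, contractile and driver genes passed after removing the GC trend alone (adjusted p = 0.000813, 0.00164 and 0.00688), collagens and senescence genes after removing the length trend alone (adjusted p = 0.0254 and 0.0339), and collagens and driver genes without the most abundant genes (adjusted p = 0.0475 and 0.0485). With only meningiomas 1 to 3, osteoblast markers, fibroblast markers, immediate early genes and the retinoic acid list passed when the genes were filtered again (adjusted p = 0.00272, 0.0114, 0.0210 and 0.0224). Over the same 15254 genes as with all libraries, osteoblast and fibroblast markers passed (adjusted p = 0.00163 and 0.0183), immediate early genes and the retinoic acid list did not (adjusted p = 0.0565 and 0.0730), and the choroid plexus list, too small to test after filtering again, lost its call (adjusted p = 0.0565). With only the other 7, collagens and B and plasma cell markers passed (adjusted p = 0.0303 and 0.0440). The glucocorticoid and choroid plexus calls were lost with fry (adjusted p = 0.0993 and 0.0997).

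The other lists did not pass camera. The Wnt list had 3 higher and 7 lower members of 14 (adjusted p = 0.631), with SFRP2 and WNT6 higher and DKK1 and DKK2 lower. The retinoic acid list had 5 higher and 6 lower of 14 (adjusted p = 0.0806), with RARRES2 higher and ALDH1A3 and RARRES1 lower. Complement had 2 higher and 4 lower of 15 (adjusted p = 0.289), with C3 higher and the regulators CD55 and CD59 lower. These 3 lists had more higher than lower members after removing the GC and length trends, which also centres the libraries. The counts were 4 and 3 for Wnt, 6 and 5 for retinoic acid, and 4 and 3 for complement. MHC class I genes had 1 higher and 3 lower of 12, and 0 and 2 when adjusted over the list alone (adjusted p = 0.0806), with TAP2 lower. B2M was lower too, and lost its call with median-of-ratios factors (adjusted p = 0.0616), after removing the GC trend (log2 difference -1.31, adjusted p = 0.231) and with only the 3 meningiomas whose deviations fell with GC content (-1.21, adjusted p = 0.149). The interferon list had 6 lower of 18, including OAS1 (adjusted p = 0.841). Contractile genes had 9 lower of 15, led by CALD1, VCL, ACTN1 and TPM1 (adjusted p = 0.132). Senescence and p53 targets had 11 lower of 14, and 12 lower and 1 higher when adjusted over the list alone, led by IL8, IGFBP3, MMP1 and FAS (adjusted p = 0.178). Meningeal transcription factors had 1 higher and 9 lower of 18, with PRRX1, ZIC1 and MEOX2 lower (adjusted p = 0.788). Immediate early genes had 4 lower of 15, and 1 when adjusted over the list alone, including NR4A2 (adjusted p = 0.552).

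Mural cell markers had 2 higher and 5 lower of 13 (adjusted p = 0.694), with COX4I2 higher and RGS5, NOTCH3 and CD248 lower. Fibroblast markers had 3 higher and 3 lower of 14, and 2 and 3 when adjusted over the list alone (adjusted p = 0.132). After removing the GC and length trends, which also centres the libraries, fibroblast markers had 6 higher and 1 lower, and mural cell markers 4 and 3. The fibroblast median went from -0.21, or 0.87 relative to that of all genes, to 1.62, where that of all genes was -2.99e-05. Astrocyte and oligodendrocyte markers had 1 higher and 3 lower of 9 (adjusted p = 0.20), with GJA1 lower. Neuron markers had 1 higher and 3 lower of 7 (adjusted p = 0.898), with NEFM and MAP2 lower. Housekeeping genes had 1 higher and 7 lower of 14 (adjusted p = 0.841), and their median lay 0.10 above that of all genes, but at -1.32 relative to it with quantile normalization. Lower members outnumbered higher ones among hypoxia (10 of 16 lower), glycolysis (9 of 16), cholesterol synthesis (13 of 19), TGF-beta (10 of 15), Hedgehog (6 of 11), solute transport (5 of 15), heat shock (4 of 12) and histone genes (4 of 10), with adjusted p values between 0.487 and 0.930. Among all 15254 tested genes 7419 were lower and 1565 higher, so such an excess is common to most lists. After removing the GC and length trends, solute transport had 7 higher and 5 lower, heat shock 3 and 3, and Hedgehog 1 and 1. Lower members still outnumbered higher ones among hypoxia, glycolysis, cholesterol synthesis, TGF-beta and histone genes. In Hedgehog, 8 were lower when adjusted over the list alone. Among heat shock genes, the chaperone HSPB1 was higher, at 1996 ± 2385 TPM against 119 ± 118, while HSPD1 and HSPA8 were lower. LDHA, which makes lactate, averaged 93.0 ± 111 TPM in tissue and 1522 ± 1034 in culture, and the growth factor VEGFA 6.08 ± 6.51 and 84.5 ± 61.5. The cystine transporter SLC7A11 averaged 0.407 ± 0.441 and 59.7 ± 19.9 TPM.

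Osteoblast and chondrocyte markers had 3 higher and 1 lower of 8, with 4 higher when adjusted over the list alone, including COL2A1. B and plasma cell markers had 1 higher of 5, Schwann cell markers 1 higher and 1 lower of 7 (0 and 1 when adjusted over the list alone), and epithelial markers 1 lower of 9, the keratin KRT7. These 4 lists had adjusted p values between 0.0540 and 0.132. Camera compares a list with all other genes, so its direction can differ from the sign of the median. It was up for arachnoid, complement, interferon, immediate early, heat shock, Wnt, mural, neuron, histone and fibroblast lists, whose medians lay below 0. The MHC class I, solute transport and astrocyte lists had a median above 0 and a mean below it. Too few adipocyte and skeletal muscle markers passed the filter for a list test (4 of 10 and 3 of 12), and CFD and TNNC2 were higher in tissue.

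Calls of single genes above were lost under settings not given beside them. With only meningiomas 1 to 3 these were CRABP1 (adjusted p = 0.320), AQP1 (0.165), CD68 (0.357), PTGDS (0.0618), NR3C1 (0.0660), MEOX2 (0.0802), CTGF (0.0939), NR4A2 (0.0746), SFRP2 (0.0636), RARRES1 (0.116) and COX4I2 (0.137), with the genes filtered again. Over the same 15254 genes these lost their calls too, as did CCNB1 (adjusted p = 0.0511), HSPB1 (0.0613), FPR1 (0.0602), WNT6 (0.0674) and COL2A1 (0.0646). A minimum of 2-fold ended the calls of CRABP1 (adjusted p = 0.0687), AQP1 (0.376), CD68 (0.384), PGR (0.836), NR3C1 (0.0710), CD3D (0.0510), S100A8 (0.0601), CSF3R (0.0920), FPR1 (0.132), PECAM1 (0.242), COL2A1 (0.0736) and CCDC153 (0.145). Removing the length trend alone ended those of CD68 (adjusted p = 0.184), NR3C1 (0.314) and NOTCH3 (0.0799), and removing the GC trend alone those of CD68 (0.117), NR3C1 (0.976), PGRMC1 (0.0842) and MT-ND5 (0.269, and 0.136 without both trends). Without a filter CRABP1 and AQP1 did not pass (adjusted p = 0.0537 and 0.0633), and with the exact Wilcoxon test AQP1 and PGR (adjusted p = 0.209 and 0.0763). PGR lost its call with quantile normalization (adjusted p = 0.109) and CD68 without the most abundant genes (adjusted p = 0.170). HOXC9 and HOXC10 passed singly with only meningiomas 1 to 3 (adjusted p = 0.00214 and 0.0212) and after removing the length trend (adjusted p = 0.0442 and 0.0400) or the GC trend (adjusted p = 0.0472 and 0.0431), and HOXC9 also with array weights (adjusted p = 0.00896). DUSP1 passed with array weights (adjusted p = 3.64e-05), without the 2 meningiomas of the other title prefix (adjusted p = 0.000905) and with only meningiomas 4 to 10 (adjusted p = 6.62e-05).

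The second comparison asked which genes varied between the 10 meningiomas, which the labels do not divide further. The 12 genes with the largest SD of log2(TPM + 1) were TMSB4XP6, LUZP6, SAA1, AGR2, TNNT3, CD177, PIGY, C4B_2, PPIAP22, C19orf33, KCNMA1 and SNRPEP4. In 5 of them, meningiomas 1 to 3 all lay above the other 7, and these were TMSB4XP6 (at least 10680 TPM against at most 565), LUZP6 (115.6 against 4.62), PPIAP22 (108.8 against 0.113), SNRPEP4 (99.7 against 13.9) and PIGY (49.2 against 28.3). The cultures also lay above those 7 in each, with TMSB4XP6 at 7117 to 15590 TPM, LUZP6 at 852 to 1060 and PPIAP22 at 294 to 381. SNRPEP4 was at 27.6 to 98.4 TPM in the cultures and PIGY at 265 to 333. All 5 are among the symbols whose reads are uncertain, so this split need not be variation between the tumours. SAA1, an acute phase protein, reached 1702 TPM in meningioma 7 and 852 in meningioma 9, with a median of 2.52. KCNMA1, a potassium channel, ranged between 2.73 and 2679 TPM. TNNT3, a troponin of fast skeletal muscle, reached 11205 TPM in meningioma 1 and 1199 in meningioma 9. PTGDS took 24.9% of all TPM in meningioma 7 and 0.0959% in meningioma 6. In meningiomas 4 to 10 the deviations from the gene means rose with GC content (rho between 0.242 and 0.552), and in meningiomas 1 to 3 they fell (rho between -0.268 and -0.0811).

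Across the 10 meningiomas, 12 relations fixed beforehand were tested, and 5 passed. DUSP1 rose with the immediate early genes, a group induced within minutes of stimulation (r = 0.928, permutation p = 0.00061, adjusted p = 0.00582; rho = 0.915, permutation p = 0.00065, adjusted p = 0.0078). Without the 2 samples farthest from the median, r was 0.780 (exact permutation p = 0.0203), within the 7 libraries whose deviations rose with GC content 0.917 and within the 8 libraries of 1 title prefix 0.831. DUSP1 also rose with NR3C1 (r = 0.855, permutation p = 0.00097, adjusted p = 0.00582; rho = 0.879, permutation p = 0.0016, adjusted p = 0.0096), with 0.810, 0.806 and 0.921 in those sets. After removing the GC and length trends, r was 0.514 (adjusted p = 0.230). The relation of DUSP1 with other glucocorticoid-induced genes (r = 0.833, permutation p = 0.0112, adjusted p = 0.0268; rho = 0.467, permutation p = 0.18, adjusted p = 0.27) rests on the farthest samples, since r was 0.209 without them. It was 0.268 within the 7 and 0.553 within the 8.

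Macrophage markers rose with MHC class II genes (r = 0.840, permutation p = 0.00149, adjusted p = 0.00596; rho = 0.721, permutation p = 0.0235, adjusted p = 0.0638). Endothelial markers rose with mural cell markers (r = 0.822, permutation p = 0.00665, adjusted p = 0.0200; rho = 0.794, permutation p = 0.00911, adjusted p = 0.0364). Without the farthest samples r was 0.563 (exact permutation p = 0.148) and 0.570 (exact permutation p = 0.134), so both rest in part on those samples. Within the 7 libraries r was 0.888 and 0.924, and within the 8 it was 0.811 and 0.872. Without the farthest samples, 0 of the 5 passed adjustment over the 12, with adjusted p values between 0.0804 and 0.799.

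The other 7 relations did not pass, with permutation p values between 0.172 and 0.848 for r (adjusted 0.344 to 0.848) and between 0.0266 and 1 for rho (adjusted 0.0638 to 1). PGR gave r = -0.0714 and rho = -0.127 with the G2 and M phase genes, and r = -0.254 and rho = 0.00606 with SSTR2. NF2 gave r = -0.117 and rho = 0.188 with the YAP targets. Macrophage markers gave r = -0.391 and rho = -0.527 with T and NK cell markers, and r = 0.244 and rho = 0.212 with the G2 and M phase genes. Interferon genes gave r = 0.371 and rho = 0.515 with MHC class I genes. Collagens gave r = 0.47 and rho = 0.709 with the TGF-beta list, and r = 0.836 without the farthest samples. Within the 8 libraries of 1 title prefix this r was 0.799 (exact permutation p = 0.0152, adjusted p = 0.0364). The title prefix with 2 meningiomas and the set of 3 are too small for values of their own.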

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

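The tests on GC content, transcript length, a scale shift, other splits of the libraries, the title prefix and the adjusted gap were chosen after the result was seen. Of 196 named genes and 45 lists examined, 20 genes and 5 lists had 1 meningioma standing apart. Its gap to the nearest other meningioma, as a share of the whole range on the log2(TPM + 1) scale, was above Dixon's critical value for 10 samples. Chance gives such a gap about 1 time in 20. Meningioma 3 accounted for 13, meningioma 2 for 7, meningioma 10 for 4 and meningioma 1 for 1.

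Meningioma 3 was highest for HLA-DRA (gap 0.523 of the range, 570 TPM), DUSP1 (0.509, 682 TPM against a median of 9.95 in the others), NR4A2 (0.616), MEOX2 (0.501), SLC38A2 (0.533), FPR1 (0.504) and RGS5 (0.583, 49.3 against 2.34 TPM). It was also highest for RPL41P1 (a gap of 1 times the range, 332 TPM against 0) and SRP9P1 (0.893), whose reads are uncertain. The same library was highest for the lists of meningeal transcription factors (0.488), glucocorticoid-induced genes (0.555) and meningioma driver genes (0.514). Meningioma 2 was highest for LUM (0.668, 675 against 3.39 TPM), PDGFRA (0.570), DKK1 (0.734, at 0.593 TPM) and the collagens and matrix list (0.484). It was lowest for CRABP1 (0.595, 2.08 against 371 TPM), WNT6 (0.493) and the T and NK cell list (0.499). Meningioma 10 was highest for PECAM1 (0.638, 64.3 against 6.89 TPM), POU2AF1 (0.527), PGR (0.576, at 1.49 TPM) and MMP1 (0.489, at 0.785 TPM). SLC2A1 was highest in meningioma 1 (0.596, 70.5 against 1.40 TPM).

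Most genes that differ were lower in tissue. A uniform shift of scale from a few abundant genes would move all GC classes alike, but the medians of the GC quartiles differed by 2.63 on the log2 scale. Such a shift alone would not give this spread. The spread cannot tell whether a shift moved the median of all genes, since a GC trend can spread the quartiles without moving it. Without the 50 most abundant, ribosomal protein and mitochondrial genes the median difference went from -1.07 to -0.55. The genes were filtered again there (16579 against 15254), so these medians cover different sets of genes. The share of lower genes went from 82.6% to 71.5%. Median-of-ratios factors gave -0.04 and 58.9%, but they centre the libraries by construction. Such a shift may therefore account for part, and how large a part was not settled. The share fell to 46.1% in the quartile of highest GC content and to 56.7% in the shortest quartile, as trends with GC content and length predict, so these may also account for part, and whether they come from RNA quality or library preparation was not tested. Of 100 splits drawn from the 286 of the 13 libraries, 1, the real one, called as many genes (8984). The highest other split, which set meningioma 3 with cultures 2 and 3, called 4304. The real split also had the largest excess of 1 direction over the other (5854, against 3898), which argues against chance for these 2 counts. The share in 1 direction cannot be judged this way. It was as large in 15 of the 16 other splits with any call, but apart from the highest these called at most 18 genes. A difference between tumour tissue and cultured cells stays open beside the trends and the shift.

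Meningiomas 4 to 10 stood apart from meningiomas 1 to 3. After removing the trends with GC content and length, the median rho within the sets still exceeded that across them by 0.105 (0.153 before). The highest other of the 120 splits into 7 and 3 gave 0.0912. The sets were drawn by their trend with GC content, so a high rank among the splits is in part built in. Any part of the trends that the splines missed would also remain. The gap therefore cannot tell whether these trends are the whole cause. Meningioma 1 carries the title prefix of the 7, so the prefix alone does not place it in the set of 3. Its median rho with the 2 libraries of the other prefix exceeded that with its own by 0.126 (between -0.231 and -0.129 in each of the 7). The sets were drawn from the same values by their trend with GC content, so this nearness in part restates them and is no separate evidence on the prefix. Both libraries of the other prefix fell in the set of 3, with an exact probability of 0.0667, so a part of the prefix in meningiomas 2 and 3 stays open with 2 such libraries. No biological explanation was tested, since the labels divide the tumours no further.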

How the results depend on the processing

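The adjustments for GC content and length, the removal of abundant genes and the sets of 3 and 7 meningiomas were chosen after seeing the data. The total of 8984 called genes stayed within 1.5 times under every alternative but a minimum of 2-fold (4876, with 469 higher and 4407 lower). The split moved to 3144 higher and 4510 lower with median-of-ratios factors, 3333 and 4187 with quantile normalization, 3502 and 3782 after length adjustment, 3271 and 3587 after GC adjustment, and 3038 and 3243 after both, where 399 genes were called in the opposite direction. These 5 settings centre the libraries, which brings the split near equal by construction. The higher count was 2834 with array weights and 2437 without abundant genes, where the cause was not tested. Leaving out each library gave 6917 to 9510 called genes, 948 to 1834 higher and 5969 to 7822 lower, with the lowest counts without a culture. Without culture 1, 2 or 3 the higher count was 948, 1004 and 1007.

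Between 12 and 17 of the lists passed when a library was left out. With an estimated correlation 0 passed (13 in the main test), 29 with fry, and 9 with the 5 TPM filter, where the HOX, T and NK cell and choroid plexus lists kept too few members to test. Of the 5 relations, 3 held with rho and 0 without the 2 farthest samples. Of the 12 most variable genes, 6 stayed with the median absolute deviation and 7 without the 2 meningiomas of the other prefix. Directions reversed for NLRC5 (0.28 with quantile normalization, 0.91 after length adjustment), PGR (0.40 after length adjustment), NR3C1 (0.33 after both adjustments) and IFIT2 (0.14 after both). These settings also centre the libraries, so genes near the median of all genes (-1.07) lose most of their difference by centring alone. PGR lay near that median, and NLRC5 went to -0.11 with median-of-ratios factors. Which part came from length or GC content was not tested. Of 196 named genes under the other settings, 3387 of 3672 values kept direction and call, 232 lost the call, 48 gained it and 5 reversed. Leaving out libraries kept 2472 of 2539. The depth is unknown, so its limit cannot be given.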

Other observations

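The tests on muscle markers and on the level of a neighbour against that of TNNT3 were chosen after the result was seen, and that on the ratios of neighbouring genes before. TNNT3 in meningioma 1 stood at 11205 TPM. Skeletal muscle in the sample would bring its other abundant transcripts. However, the muscle markers compared had a median of 0.028 TPM there, with ACTA1 at 0.029 and CKM at 0.027. This median left out TNNT3 and the other troponin T gene among the 12 markers in the list, so it does not bear on that gene. DES stood higher there, at 3.434 TPM against a median of 0.09996 in the other 9 meningiomas. TNNC2 stood lower, at 6.396 against 20.5 TPM. Of the 6 nearest measured genes, LSP1 was 21.2 times its median in the other 9 meningiomas, at 142 TPM, a rise that reads shared with a neighbour would bring. That level was 0.0127 of that of TNNT3, which argues against reads of LSP1 as the whole source, and activity shared across the locus was not tested. INS-IGF2 was 12.1 times its median at 1.97 TPM, IGF2 was at 834 against 176 TPM and TNNI2 at 1.56 against 2.05.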
